A study of Mus musculus with 12 samples.

How the data were processed

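RNA was sequenced from 12 samples of MGPP3 mouse glioma cells, in 4 groups of 3 by the titles in the labels. The libraries were made with a directional kit, per the labels' protocols. The submitters' processing notes name kallisto, DESeq2 and the mouse genome build mm10, without versions or the role of each, and other steps by the authors are not given in the sources used here. The deposited table is named as gene-level TPM from kallisto, and its values were inspected but not used for any result. Its value columns are headed by codes, and each code was searched for, ignoring case and punctuation, in every label of every sample and in the series' title and design text. Columns were to be assigned to samples by name only, and all 12 columns were left out because 0 matched. The model, gene lists and alternatives that had been fixed before the data were examined were not run, since each needs the group of every column. The depth of the libraries is unknown.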

Results

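The series holds RNA sequencing of MGPP3 cells, a mouse line of proneural glioma that lacks Pten and p53 by its labels. The labels give 12 samples in 4 groups of 3. One group was naive cells. The other groups were lines that had acquired resistance to ispinesib, alisertib or volasertib. The design text describes the resistant lines as derived independently of one another. The titles alone do not say whether samples within a drug group were separately derived lines or cultures of the same line. Ispinesib inhibits the mitotic kinesin KIF11, alisertib inhibits Aurora kinase A, and volasertib inhibits the Polo-like kinase PLK1, so each drug disturbs the mitotic spindle through a different protein. The comparisons that this design implies are each resistant group against naive cells, the resistant groups together against naive cells, and each pair of drugs against each other. They address which genes and pathways changed with acquired resistance, and which changes were shared between the drugs.

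None of these comparisons was made here. The expression table examined here has 12 columns of values, headed by short codes. The codes were compared with every label of every sample, and 0 of the 12 columns matched one. Which column belongs to naive cells and which to each resistant group is therefore not known from the sources used here. Expression values were not used to assign the groups, because groups assigned from expression would decide the outcome of the comparisons. Column order was not used either, because columns were to be assigned by name only. No expression level, fold change or test is reported for any gene.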

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

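The number of value columns matched to a sample was 0 of 12 by name. It was also 0 when only the digits of each code were searched for in the sample labels, with or without leading zeros. These searches were added after the table had been seen. They are a weak check, because a shared number alone would not have shown that a column belonged to a sample. Alternatives of pseudocount, filter, scaling, variance model, library weights, set test and left-out replicates were not run. No paired analysis was possible because the columns carry no replicate numbers and no groups. The titles number the samples within each group, and these numbers alone do not show that samples were paired across groups.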
